A study of Mus musculus with 2 samples.

How the data were processed

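Total RNA from 2 sorted populations of mouse splenic dendritic cells (DCs) was labelled with biotin as cRNA and hybridised to Affymetrix arrays, 1 array per population. Each array carried 45101 probe sets, and each probe set is a group of short oligonucleotide probes for a transcript. The deposited table holds log2 signal values per probe set, and RMA was the processing tool used by the authors, per the submitters' processing notes. RMA corrects background, quantile-normalises the arrays and combines the probes of a probe set by median polish. Its version and the set of arrays normalised together are not given in the sources used here. Because quantile normalisation gives arrays nearly the same distribution, a shift shared by most transcripts would not be visible. The sorted values of the 2 columns differed by at most 0.109, and 7.30% of probe sets held the same value on both arrays. Background also compresses the difference of a transcript that is dim on 1 array. No detection calls were used here.

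Probe sets were named through the platform annotation supplied with the table, and symbols were checked by gene identifier against the RefSeq gene table of the GRCm38.p6 assembly. Of the 45101 probe sets, 34958 had a single gene symbol and 932 had several. The remaining 9211 were not listed in the annotation and are unnamed here. The identifier matched for 34754 of the single-gene probe sets, and the other 204 kept the annotation's symbol. Probe sets with several symbols or none stayed out of the gene comparison. Of these 10143 probe sets, 3465 reached the floor described next. The 34958 probe sets covered 18194 genes. Where a gene had several probe sets, the probe set with the highest mean over both arrays stood for it. A gene counted as measured where the higher of its values reached the median of all values in the table, a log2 signal of 3.85. This floor left 11404 measured genes, 62.7% of those on the array, and 5183 of them were measured by more than 1 probe set. The other 6790 genes were not above it on either array. All columns of the table were used. Genome coordinates are not given, because the files name no genome build.

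The comparison is the log2 difference between the arrays, CD8+ minus CD8-. With 1 array per population there are no replicates, so no test was made, no p-value is given, and a difference cannot be separated from variation between mice, sorts or hybridisations. Genes were described by size, with a threshold of 2-fold. Where the dimmer value lay below the floor, the fold is given as "at least", with the floor in place of the dimmer value. The number of arrays limits the precision of every value. Some measures of technical spread within the pair were available. The 45 control probe sets for bacterial and phage transcripts differed by 0.07 ± 0.12 (mean ± SD over probe sets). Across 5183 genes measured by several probe sets (14017 probe sets), the pooled SD of the difference between probe sets of a gene was 0.30. Neither measures variation between mice or sorts.

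In all, 39 gene lists were fixed before the data were examined, from general knowledge of DCs and spleen. They held 680 entries, of which 60 had no single-gene probe set here. For each list, the median log2 difference over its measured genes was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. This percentile describes these arrays and is not a test of the populations. A list was said to stand apart where it had at least 5 measured genes and its percentile was below 2.5 or above 97.5. Individual genes were named by a rule fixed at the same time. It took the 12 largest differences in each direction among genes whose measured probe sets all had the same sign, without predicted genes. It also took up to 4 genes with the largest differences in each list, all genes of the sort marker list and all measured Toll-like receptors. Genes named outside the rule are marked as chosen after their values were seen.

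Alternatives were centring each array on its median, subtracting a lowess trend of the difference on signal (span 0.3), no filter or a filter at the 75th percentile, averaging all probe sets of a gene, leaving out probe sets prone to cross-hybridisation (names ending in _x_at or _s_at), and thresholds of 1.5-fold and 4-fold. Setting values below the floor to the floor was added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. They were tested on simulated data, a pair of arrays with noise of SD 0.2 each and 11297 measured genes. All 100 genes planted at 4-fold were recovered at the 2-fold threshold, as were 93 of 100 planted at a log2 difference of 1.5, with 6 unchanged genes past it. Changes were planted only in genes with a mean log2 signal of at least 6 and without background compression. Recovery of dim genes was therefore not tested, and the noise was assumed, not taken from replicates. Of 200 random lists drawn from unchanged genes, 3% stood apart. The noise was independent between genes, so this share does not carry over to lists of genes that vary together.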

Results

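The data compared the gene expression of the main subsets of conventional DCs in mouse spleen, those with and without CD8α at their surface. DCs are the cells that present antigen to T cells. They were expanded in C57BL/6 mice by injecting B16 melanoma cells, a mouse tumour line, that produced Flt3 ligand, a cytokine that drives DC development. Between 10 and 12 days later, spleen DCs were enriched magnetically and sorted as CD11c+ cells without CD3 or B220, surface markers of T cells and of B cells and plasmacytoid DCs. The sort separated CD8α+ from CD8α- cells, and neither population was stimulated afterwards. Each population was measured on 1 array, and no value here has a replicate. Values below a log2 signal of 3.85, the floor used here, were treated as near background, without detection calls. The arrays had medians of 3.86 (CD8+) and 3.83 (CD8-) on the log2 scale, and they correlated with r = 0.92 across the 11404 measured genes, which are not independent replicates. The comparison asks how the transcripts of the subsets differ. The place of a list's median among matched random lists is given as a description of these 2 arrays. The lists share genes, so those that stand apart are not independent of each other. Of the 21 measured CD8- DC signature genes, 18 are also in another list, as are 12 of the 22 CD8+ DC signature genes.

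Of the genes for the sort and selection markers, Cd8a differed most. Cd8a, which encodes CD8α, had a log2 signal of 11.29 in CD8+ DCs and 5.15 in CD8- DCs, a 70.6-fold difference. Its 5 measured probe sets differed by 1.73 to 6.26. The CD8β gene Cd8b1 was below the floor on both arrays (3.05 and 2.66). Among the other genes of sorted or selected proteins, Itgax, which encodes CD11c, was 9.80 in CD8+ and 10.69 in CD8- DCs. Flt3, the receptor for the ligand used for expansion, is in the sort marker list but was not used in the sort. It was at 10.07 and 9.80. Ptprc, whose B220 isoform marks B cells, was 11.69 and 12.42, and its 2 measured probe sets differed by -0.73 and 0.01. These values were not resolved by isoform. The T cell genes Cd3e (4.76 and 4.90) and Cd3d (3.19 and 3.10) were low on both arrays. Cd8a was the 1 gene of the 5 measured in the sort marker list to reach 2-fold (list median -0.14, within the random range).

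More genes were higher in CD8- DCs than in CD8+ DCs, and by larger folds. At the 2-fold threshold, 405 genes (3.55% of those measured) were higher in CD8+ DCs and 681 (5.97%) were higher in CD8- DCs. At 4-fold the counts were 98 and 239. Above 16-fold, Cd8a alone was higher in CD8+ DCs, against 60 genes in CD8- DCs. With values below the floor set to it, the counts were 371 and 633 at 2-fold, 90 and 208 at 4-fold, and 1 and 47 at 16-fold. Of the 509 genes past 2-fold with several measured probe sets, 483 (94.9%) had all of them in the same direction.

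**Figure D1:**
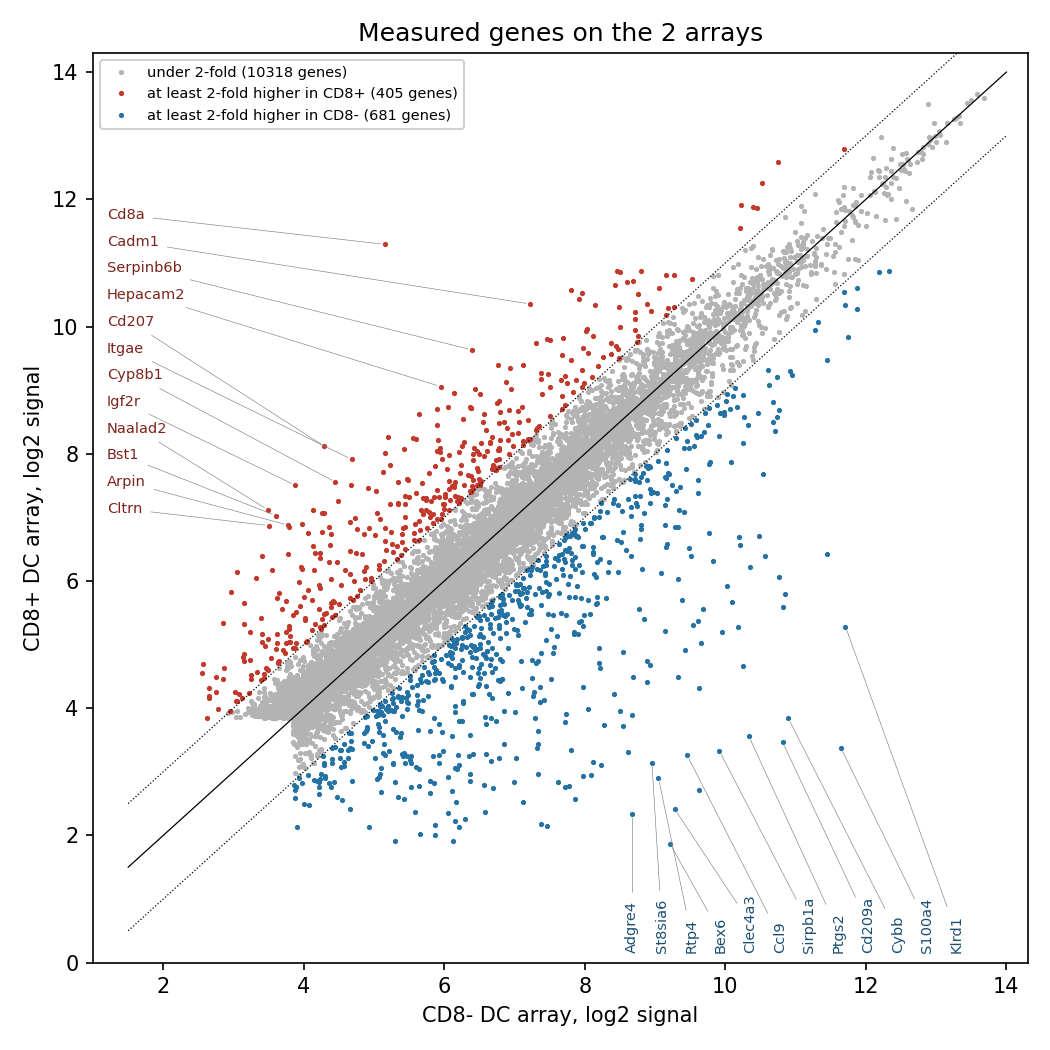
Log2 signal of each of the 11404 measured genes on the CD8- array (horizontal axis) and the CD8+ array (vertical axis), 1 point per gene, with the line of equality solid and the 2-fold lines dotted. Red points are the 405 genes at least 2-fold higher in CD8+ DCs and blue points the 681 at least 2-fold higher in CD8- DCs, and the 12 largest differences that the naming rule took in each direction are labelled.

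After Cd8a, the largest differences in favour of CD8+ DCs lay between 8-fold and 15-fold. Cd207, which encodes the lectin langerin, was 14.2-fold higher (8.12 against 4.29). Igf2r, the cation-independent mannose 6-phosphate receptor, was 12.4-fold higher (7.50 against 3.88, just above the floor). Itgae, which encodes the integrin CD103, was 9.39-fold higher and the adhesion molecule gene Cadm1 was 8.77-fold higher (10.35 against 7.22, 4 probe sets between 3.13 and 3.71). Serpinb6b was 9.40-fold, Cyp8b1 8.59-fold and Hepacam2 8.57-fold higher. Naalad2, Bst1, Cltrn and Arpin were below the floor in CD8- DCs and were at least 9.66-fold, 9.06-fold, 8.14-fold and 8.18-fold higher in CD8+ DCs. The 2 probe sets of Naalad2 differed by 1.18 and 3.63.

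In favour of CD8- DCs, the largest difference was that of S100a4, a calcium-binding protein gene, at 11.64 against 3.38, or at least 222-fold. Cd209a, a C-type lectin gene of the DC-SIGN family, was at least 125-fold higher, and Cybb, which encodes the catalytic gp91phox subunit of the phagocyte NADPH oxidase, at least 132-fold (10.89 against 3.84). The 3 Cybb probe sets differed by -7.05 to -4.33. Ptgs2, the inducible cyclooxygenase gene, was at least 89.8-fold higher (10.33 against 3.56). The receptor genes Sirpb1a, Clec4a3 and Adgre4 were at least 67.2-fold, 43.2-fold and 28.5-fold higher, and Klrd1, which encodes CD94, was 86.1-fold higher (11.71 against 5.28). Sirpb1a and Clec4a3 belong to families of similar genes, so cross-hybridisation cannot be ruled out. The chemokine gene Ccl9 was at least 48.8-fold higher, Bex6 at least 41.3-fold, the interferon-inducible gene Rtp4 at least 36.8-fold and the sialyltransferase gene St8sia6 at least 34.5-fold.

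Most textbook signature genes of each subset differed in the direction of their name. Of 22 measured CD8+ DC signature genes (Cd8a not included), 18 were at least 2-fold higher in CD8+ DCs and none was lower by that much. Their median difference was 2.06, above all 10000 random lists. Beside Cd207, Itgae, Cadm1 and Hepacam2, they held Xcr1, the XCL1 receptor gene (5.36-fold higher, 10.88 against 8.45), the scavenger receptor gene Cd36 (5.10-fold) and Tlr3 (4.25-fold). Among the transcription factors of this list, which were chosen after their values were seen, Irf8 was 3.22-fold higher (11.91 against 10.23), while Id2 (1.63-fold) and Batf3 (1.59-fold) stayed under 2-fold. The integrin gene Itgb7, chosen in the same way, was the 1 member lower in CD8+ DCs (9.07 against 9.58). Of 21 measured CD8- DC signature genes, 15 were at least 2-fold higher in CD8- DCs and none was lower by that much. Their median difference was -2.94, below all random lists, or -2.35 with values below the floor set to it. The integrin gene Itgam, which encodes CD11b, was at least 15.2-fold higher in CD8- DCs, the fractalkine receptor gene Cx3cr1 at least 15.6-fold, the CD47 receptor gene Sirpa 18.4-fold and the M-CSF receptor gene Csf1r 17.9-fold. The 3 measured probe sets of Csf1r differed by -4.17 to -1.82. Of the other members, chosen after their values were seen, Cd4 was 3.90-fold higher in CD8- DCs, whereas Notch2 (10.53 and 10.43), Rbpj (9.57 and 9.29) and Lyz2 (10.69 and 10.11) were slightly higher in CD8+ DCs.

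All 22 CD8+ DC signature genes lay above the floor in CD8- DCs, where they had a median signal of 8.48 and a median of 23.9% of their CD8+ level (quartiles 16.7% and 35.8%). Cd8a had 1.42% of its CD8+ level there. Of the 21 CD8- DC signature genes, 11 were below the floor in CD8+ DCs, and their median signal was 7.77 in CD8- and 3.72 in CD8+ DCs. As measured, the 21 genes had a median of 13.1% of their CD8- level in CD8+ DCs (quartiles 5.57% and 50.6%), a range that overlaps that of the CD8+ DC signature. The median falls on Tlr7, which was at 3.26 in CD8+ DCs. Shares of genes below the floor rest on near-background values, so the ranges are not compared on equal terms.

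**Figure D2:**
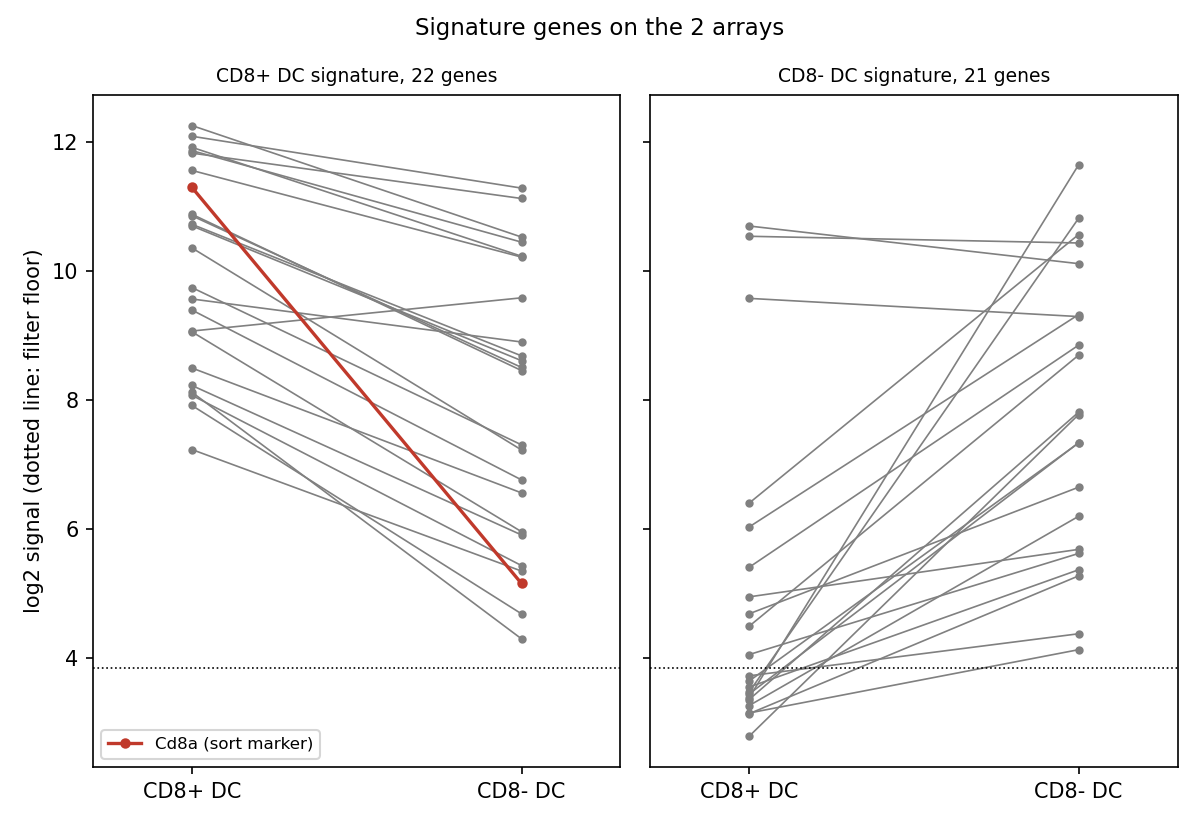
Log2 signal of the measured signature genes on the CD8+ and the CD8- array, with a line joining the values of each gene, for the 22 CD8+ DC signature genes (left, with the sort marker Cd8a in red) and the 21 CD8- DC signature genes (right). The dotted line is the floor of 3.85, above which every gene of the left panel stays on both arrays and below which 11 genes of the right panel lie in CD8+ DCs.

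Of 38 measured transcription factors of DC and myeloid development, 10 were at least 2-fold higher in CD8- DCs and 2 in CD8+ DCs, with a median difference of -0.31 that lay below all random lists. With values below the floor set to it, 8 were higher in CD8- DCs. Spib was at least 21.4-fold and Irf4 at least 11.2-fold higher in CD8- DCs, Klf4 was 10.9-fold higher and the NF-κB subunit gene Relb 4.28-fold higher. The 2 factors higher in CD8+ DCs were Irf8 and, chosen after its values were seen, Mycl (3.48-fold).

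Among genes of innate recognition, Toll-like receptors divided between the subsets, while most genes of the other lists were higher in CD8- DCs. Among 9 measured Toll-like receptors, Tlr1 (at least 26.0-fold) and Tlr7 (at least 5.09-fold) were higher in CD8- DCs, and Tlr3 (4.25-fold) and Tlr12 (3.69-fold) were higher in CD8+ DCs. The probe sets of Tlr12 differed by 0.83 and 1.88. The list median of -0.03 lay within the random range, but it was -0.69 with the stricter filter and -0.34 with all probe sets averaged, where the list stood apart. The other 5 were under 2-fold, at 7.29 and 8.27 in CD8+ and CD8- DCs for Tlr2, 5.90 and 6.59 for Tlr6, 5.59 and 5.62 for Tlr4, 8.69 and 8.67 for Tlr13, and 5.62 and 5.43 for Tlr9. Of 16 adaptors and cytosolic sensors, 4 were at least 2-fold higher in CD8- DCs and none in CD8+ DCs (median -0.30, above only 66 of the random lists). They were the inflammasome protease gene Casp1 (4.32-fold), the RNA sensor gene Ifih1 (2.75-fold), Sting1 (log2 difference -1.32) and Nod1 (2.26-fold). Of 13 C-type lectins, 8 were at least 2-fold higher in CD8- DCs and 2 in CD8+ DCs (median -1.19, below all random lists, or -0.87 and 6 genes higher in CD8- DCs with values below the floor set to it), among them Clec7a, which encodes the β-glucan receptor dectin-1 (33.1-fold), and Clec4a2 (at least 16.2-fold, with probe sets at -5.28 and -1.01). The 2 higher in CD8+ DCs were Cd207 and Ly75, which encodes DEC-205 (4.98-fold, chosen after its values were seen). Of 9 Fc and complement receptors, 4 were at least 2-fold higher in CD8- DCs and none in CD8+ DCs (median -0.68, above 4 of the random lists). They were Itgam, the Fc receptor common γ chain gene Fcer1g (26.0-fold), Fcgr3 (at least 2.86-fold) and Fcgr4 (2.73-fold).

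The genes of the class II molecules themselves were bright and nearly equal on both arrays. Chosen after their values were seen, H2-Aa (13.60 and 13.68), H2-Ab1 (13.20 and 13.16), H2-Eb1 (12.99 on both arrays) and the invariant chain gene Cd74 (13.28 and 13.29) had log2 signals near the top of the range. Saturation could compress a difference there and was not tested. Of the 16 measured genes of the class II pathway, 5 were at least 2-fold higher in CD8- DCs and none in CD8+ DCs (median -0.18, above 205 of the random lists), a list that did not stand apart with the stricter filter. They included Lgmn, a lysosomal endopeptidase gene (5.77-fold), H2-DMb2 (3.76-fold), the thiol reductase gene Ifi30 (2.40-fold) and the cathepsin gene Ctsd (2.21-fold). None of the 17 class I pathway genes reached 2-fold, yet 13 were higher in CD8+ DCs and the median of 0.46 exceeded 9999 of the random lists. Among them the immunoproteasome subunit gene Psmb9 and the peptide transporter gene Tap2 were each 1.83-fold higher, and the chaperone genes Pdia3 and Calr were 1.75-fold and 1.59-fold higher. Of 19 lysosomal genes, 6 were at least 2-fold higher in CD8- DCs, with Ctsa (log2 difference -2.32), Ctsh (2.51-fold) and Ctsc (2.44-fold) among them, and Gusb was 4.22-fold higher in CD8+ DCs (median -0.38, above 1 of the random lists). The other measured probe set of Ctsa differed by -0.09.

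Costimulation and maturation genes were mostly higher in CD8- DCs. Of 16 measured, 9 were at least 2-fold higher there and 2 in CD8+ DCs (median -1.21, below all random lists). The 4-1BB ligand gene Tnfsf9 was 12.6-fold higher, the cytokine signalling inhibitor gene Socs3 6.61-fold, and the PD-1 ligand genes Cd274 4.81-fold and Pdcd1lg2 at least 3.17-fold. Socs3 was under 2-fold without the probe sets prone to cross-hybridisation. The genes higher in CD8+ DCs, chosen after their values were seen, were Cd86 (3.51-fold) and the chemokine gene Ccl22 (2.72-fold). Cd83 (11.40 and 11.38), Cd40 (7.23 and 7.93) and Cd80 (6.94 and 7.59), also chosen after their values were seen, were under 2-fold.

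Of 9 measured chemokine receptors in the fixed list, 6 were at least 2-fold higher in CD8- DCs, including Cx3cr1, Ccr1 (at least 8.82-fold) and Ccr2, the receptor for monocyte chemoattractants (9.81-fold), and 3 were so in CD8+ DCs, including Xcr1 (median -1.37, above 1 of the random lists). The 4 measured probe sets of Ccr2 differed by -3.52 to -1.03. Of 12 chemokines, 4 were at least 2-fold higher in CD8- DCs, among them Ccl9, Ccl3 and Ccl5 (11.3-fold). Ccl3 was at 7.02 in CD8- DCs and at 3.21, below the floor, in CD8+ DCs. Its log2 difference of -3.80 therefore rests on a near-background value. Of the 12, 2 were at least 2-fold higher in CD8+ DCs, among them the CXCR3 ligand gene Cxcl9 (5.93-fold, 10.52 against 7.96). The chemokine median of 0.08 lay within the random range, but with the stricter filter it was -0.998 over 9 genes and the list stood apart. Among 12 cytokines, 3 were at least 2-fold higher on each side, and their median (-0.06) also lay within the random range. With values below the floor set to it, 2 were higher in CD8+ DCs. Il12b, the gene of the p40 subunit of IL-12 and IL-23, was 4.82-fold higher in CD8+ DCs (6.93 against 4.66) and Il15 3.26-fold higher, while lymphotoxin β (Ltb) was 27.1-fold and the IL-1 receptor antagonist gene Il1rn at least 2.68-fold higher in CD8- DCs. Of 25 cytokine receptors, 5 were at least 2-fold higher in CD8- DCs and none in CD8+ DCs (median -0.28, above 12 of the random lists), with Csf1r and the decoy receptor gene Il1r2 (6.88-fold) leading. With values below the floor set to it, 3 of the 5 stayed past 2-fold, without Il7r and Il18r1.

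Of 26 measured interferon-stimulated genes, 19 were lower and 6 higher in CD8+ DCs, and 11 were at least 2-fold higher in CD8- DCs and none in CD8+ DCs (median -0.87, below all random lists). Rtp4, Oasl2 (at least 14.6-fold), Ifit3 (12.5-fold) and Oas1a (7.78-fold) led, while Irf7 (8.24 and 8.17) and Mx1 (7.88 and 6.96), chosen after their values were seen, were not lower in CD8+ DCs. All 26 measured cell cycle genes were lower in CD8+ DCs and 8 were so by at least 2-fold (median -0.79, below all random lists). Nusap1 (2.95-fold), Kif11 (2.56-fold), Bub1 (2.53-fold) and Ccna2 (2.44-fold), which act in mitosis or its onset, differed most.

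**Figure D3:**
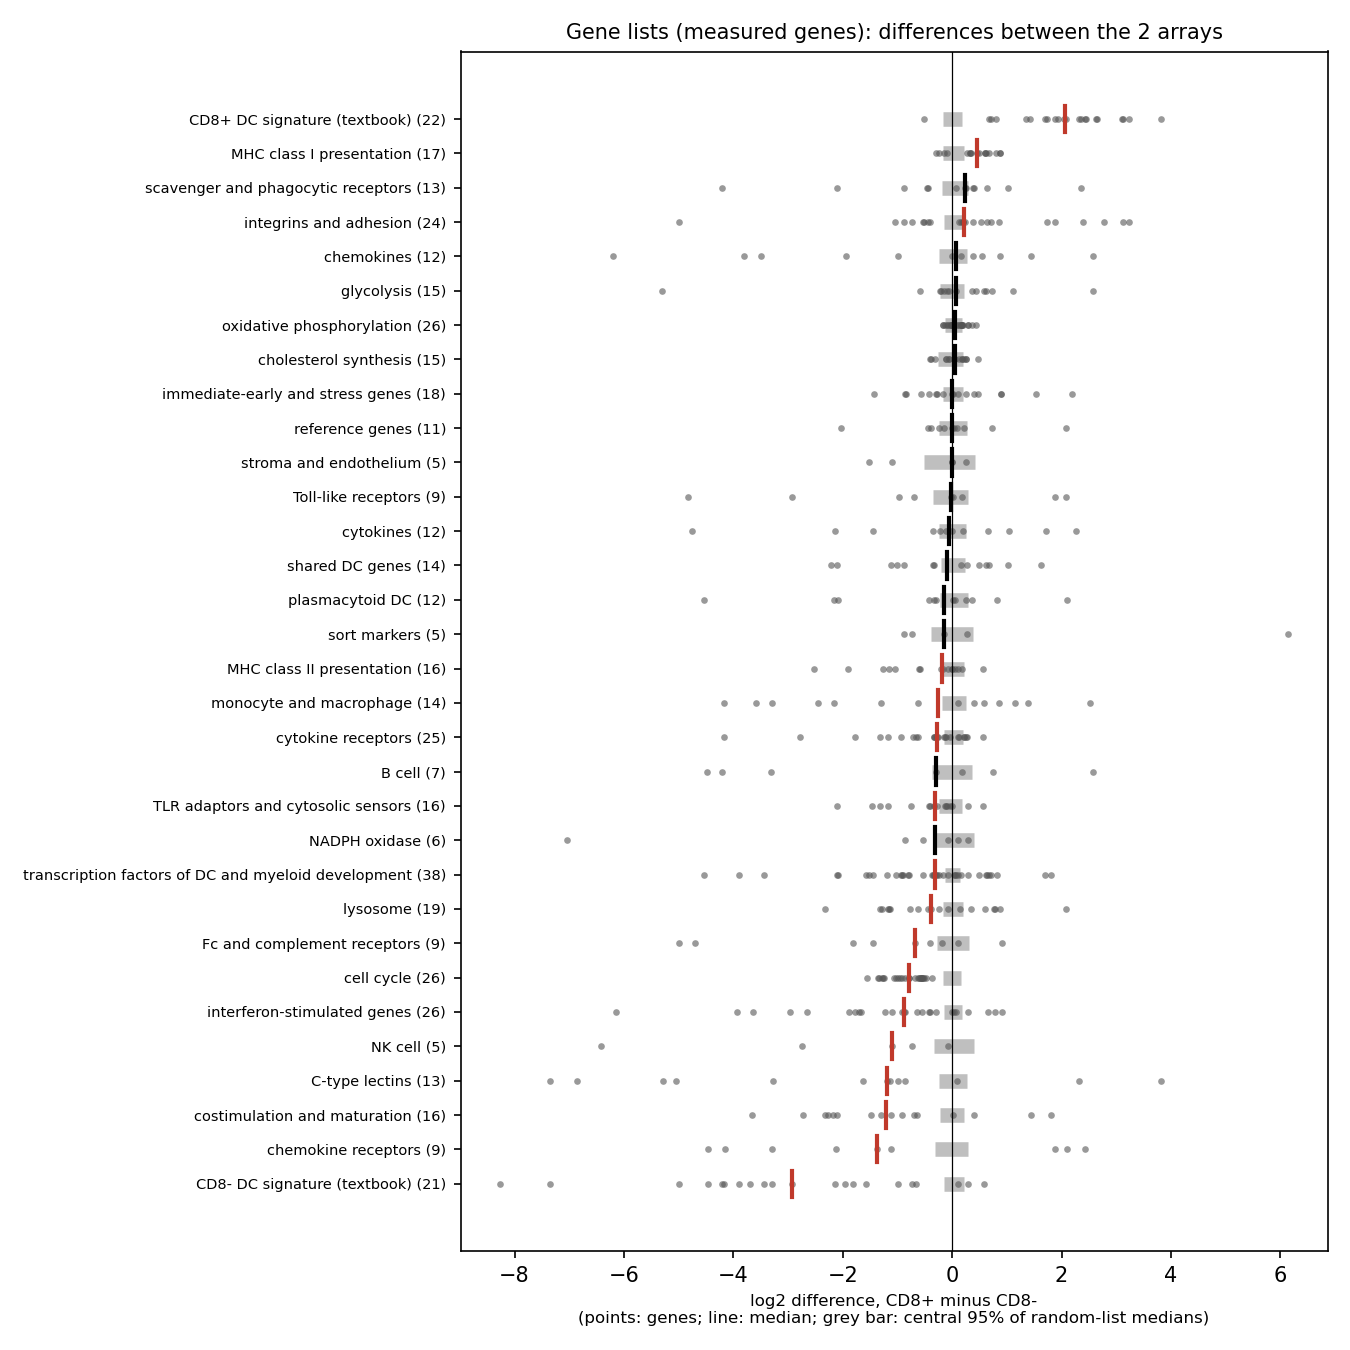
Log2 difference (CD8+ minus CD8-) of the measured genes of each list with at least 5 of them, 1 point per gene, with the number of measured genes in brackets. Vertical lines are list medians, red where the list stood apart from the random lists, and grey bars are the central 95% of the medians of 10000 matched random lists. The CD8+ DC signature median lies at 2.06, that of the CD8- DC signature at -2.94 and that of the cell cycle at -0.79.

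In the integrin and adhesion list, 6 of 24 genes were at least 2-fold higher in CD8+ DCs and 2 in CD8- DCs (median 0.22, above 9838 of the random lists), with the tetraspanin gene Cd81 6.86-fold higher in CD8+ DCs. This list no longer stood apart when all probe sets of a gene were averaged or when probe sets prone to cross-hybridisation were left out. Oxidative phosphorylation genes (26 measured, median 0.06), cholesterol synthesis genes (15 measured, median 0.05) and immediate-early and stress genes (18 measured, median 0.00) had medians within the random range, and no member of the first 2 lists reached 2-fold. Of the immediate-early genes, the growth response factors Egr3 (4.59-fold) and Egr2 (2.90-fold) were higher in CD8+ DCs and Atf3 (2.70-fold) was higher in CD8- DCs. The Egr3 probe sets disagreed, at 0.47 and 2.20. Glycolysis genes (15 measured, median 0.07) included the glucose transporter gene Slc2a3, at least 27.3-fold higher in CD8- DCs, and the hexokinase gene Hk3, 5.98-fold higher in CD8+ DCs. In the NADPH oxidase list (6 measured, median -0.31), Cybb stood alone past 2-fold, beside Rac2 (8.91 and 9.78), Cyba (10.90 and 11.44) and Ncf4 (9.39 and 9.11). The scavenger receptor list (13 measured, median 0.23, or 0.08 with values below the floor set to it) had 2 genes past 2-fold on each side, Cd36 and Havcr2 (2.04-fold) in CD8+ DCs and Sirpa and Axl (at least 2.92-fold) in CD8- DCs. Havcr2 was under 2-fold after centring, and Axl when all probe sets were averaged. Genes shared by DCs (14 measured, median -0.09) and reference genes (11 measured, median 0.00) lay within the random range, although Tfrc was 4.10-fold higher in CD8- DCs and Gusb 4.22-fold higher in CD8+ DCs.

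Lists of markers of other cell types that a spleen DC sort could hold were also compared. Of 7 measured B cell genes, Cd22 (22.3-fold), Cd72 (18.4-fold) and Cd79b (at least 6.72-fold) were higher in CD8- DCs, and Fcrla was 5.99-fold higher in CD8+ DCs (list median -0.30, within the random range). Of 5 measured NK cell genes, Klrd1, Tbx21 (at least 2.81-fold) and Klre1 (2.15-fold) were higher in CD8- DCs (list median -1.10, above 6 of the random lists), but without the filter the median of the 12 NK cell genes on the array was 0.0493 and the list no longer stood apart. Klrk1, which encodes NKG2D, was bright on both arrays (9.44 in CD8+ and 10.17 in CD8- DCs). Of 14 measured monocyte and macrophage genes, 6 were at least 2-fold higher in CD8- DCs and 3 in CD8+ DCs (median -0.26, above 64 of the random lists). Csf1r, Ccr2 and Adgre1, which encodes F4/80 (12.1-fold), were on the first side and Treml4 (5.71-fold) on the second. With values below the floor set to it, 5 were higher in CD8- DCs. This list did not stand apart without the filter or with the stricter one. Of 12 plasmacytoid DC genes, Spib, Tcf4 (4.24-fold) and Smim5 (at least 3.86-fold) were higher in CD8- DCs and Ccr9 (4.26-fold) in CD8+ DCs, within the random range (median -0.14). The list stood apart, lower in CD8+ DCs, with all probe sets averaged (median -0.31) and without the probe sets prone to cross-hybridisation (median -0.30). Ccr9 was under 2-fold when all probe sets were averaged. Fewer than 5 genes were measured in the T cell (4, median -0.57), plasma cell (4, median 0.07), erythroid (4, median -0.54), platelet (4, median 0.22), melanoma (4, median 0.00) and neutrophil (2, median 0.44) lists. In these, the IL-7 receptor gene Il7r (log2 difference -1.17), Prdm1 (-1.45), Tfrc and Car2 (-1.51) were at least 2-fold higher in CD8- DCs, but for Il7r and Prdm1 not with values below the floor set to it. The T cell list stood apart without the filter (median -0.14 over 13 genes). In the plasma cell list, the immunoglobulin heavy chain gene Ighm (9.83 and 9.93) and Xbp1 (10.21 and 9.92) were bright in both CD8+ and CD8- DCs. The stroma and endothelium list (5 measured, median 0.00) had Pecam1 (2.88-fold) and Kdr (2.15-fold) higher in CD8- DCs. Xist, expressed from the inactive X chromosome of female cells, was at 10.73 and 11.04, and it was the only sex-linked gene measured.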

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

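The setting in which values below the floor were set to it was chosen after seeing the data. The counts of genes at least 2-fold higher in CD8+ and CD8- DCs stayed within 1.5 times the reported 405 and 681 with each alternative normalisation, filter and choice of probe sets, and 62.3% to 65.6% of the genes past 2-fold were higher in CD8- DCs. Other thresholds changed them, to 968 and 1314 at 1.5-fold and to 98 and 239 at 4-fold. The CD8- DC signature median was -2.54 without the filter, -3.69 with the stricter one, -2.19 with all probe sets averaged and -2.35 with values at the floor. The CD8+ DC signature median was 1.90 with all probe sets averaged. The NK cell median changed sign to 0.0493 without the filter, which adds genes below the floor, and Ddr1, at -6.91, changed to 0.0602 without the probe sets ending in _x_at or _s_at, when another probe set stood for it. Without the filter the CD8- DC signature gained Tlr5 (-0.158), which moved its median. With values at the floor its median fell on Tlr7, whose CD8+ value was raised to the floor. For the remaining shifts the cause was not tested. Of the 17 lists that stood apart, 17 did so after centring, after the lowess trend was subtracted and with values at the floor, 16 with averaged probe sets and without the _x_at and _s_at probe sets (integrins lost in both), and 15 without the filter. With the stricter filter 14 of 16 did. Lists that stood apart under an alternative alone were Toll-like receptors and chemokines with the stricter filter, Toll-like receptors and plasmacytoid DC with averaged probe sets, plasmacytoid DC without the _x_at and _s_at probe sets, and T cell without the filter. Of 126 named genes past 2-fold, 124 stayed so after centring, 125 after the lowess trend, 122 with averaged probe sets and 122 with values at the floor. No paired analysis was possible because the labels give no replicate numbers and each group has 1 array, and for the same reason no array was left out in turn. Signal over background limits the folds of dim genes, since 73 of the 405 and 174 of the 681 genes had their dimmer value below the floor. Folds of genes whose dimmer value lay little above the floor may be limited in the same way.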

Other observations

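The tests here were all chosen only after the result was seen, and the genes named here that no earlier rule took were chosen after their values were seen. Genes were grouped by the stem of their symbol, giving 294 groups with at least 6 measured genes, each placed among 2000 matched random lists. The Ms4a group of membrane proteins had the lowest median, at -3.40, below all random lists, and 6 of its 8 measured genes were at least 2-fold higher in CD8- DCs. With values below the floor set to it, the median was -2.80 and 5 genes were. Ms4a4c was 37.6-fold higher, Ms4a6b 17.5-fold and Ms4a6c 17.2-fold, while Ms4a1, which encodes the B cell protein CD20, was 1.68-fold higher in CD8+ DCs. The members are similar in sequence, and the probe sets of Ms4a6c differed by -4.11 and -0.72. The Frizzled group of Wnt receptors had the highest median, 0.56 over 7 genes, but most of them were dim and the median was 0.15 with values below the floor set to it. Fzd1 was 5.85-fold higher in CD8+ DCs and Fzd7 2.01-fold, the latter under 2-fold after centring, after the lowess trend was subtracted and with all probe sets averaged.

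Among single genes outside these groups, Tgm2, which encodes the crosslinking enzyme tissue transglutaminase, was 48.3-fold higher in CD8- DCs (10.25 against 4.66), with 5 probe sets between -6.28 and -2.61. The 6 measured probe sets of the collagen receptor gene Ddr1 ranged from -6.91 to 0.06, so no single difference describes it. No gene at a log2 signal of 8 or more in CD8+ DCs was below the floor in CD8- DCs, against 18 genes in the other direction. Of the 3465 probe sets without a single gene name that reached the floor, 101 were at least 2-fold higher in CD8+ DCs and 207 in CD8- DCs, and these are unnamed here.

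CD8+ DC signature genes kept a sizeable share of their CD8+ level on the CD8- array. Carry-over of CD8+ DCs into the CD8- sort, irrespective of their CD8α, would bring Cd8a in the same share. Cd8a kept 1.42%, while the lower quartile of the signature genes was 16.7%. This argues against carry-over of that kind as the whole source. The sort selected on CD8α itself, so CD8+ DCs with little of it that fell into the CD8- gate could keep a low Cd8a share. The comparison cannot decide on carry-over of such cells. Bulk RNA gives no values per cell. It therefore cannot separate low expression in all CD8- DCs from CD8- sorted cells with the CD8+ DC programme but without Cd8a. The lowest share, 7.06% for Cd207, may come from either or from background. Cd207 was at 4.29 in CD8- DCs, little above the floor and below the T cell gene Cd3e (4.90). The median signal of the signature genes there was 8.48. A difference between the subsets themselves stays open and untested.

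All 26 measured cell cycle genes were lower on the CD8+ array. Random lists matched on mean signal share any offset of the arrays and any trend of the difference with signal. The cell cycle median of -0.79 lay below the central 95% of their medians, whose lower bound was -0.17, which argues against either as the whole cause. This is the comparison by which the list was first found to stand apart, so it adds no independent support. The list also stood apart after each array was centred and after the lowess trend was subtracted. A difference between the subsets, the mice or the sorts stays open and was not tested, because each group has 1 array.

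Some B cell and NK cell genes were higher on the CD8- array. B cells in the CD8- sort would bring the other B cell genes. The median CD8- minus CD8+ difference over the 13 list genes on the array was 0 (SD 2.04 over genes), and Cd79a was at 3.35 in CD8- DCs. In contrast, Cd79b was at 6.59 in CD8- and 3.28 in CD8+ DCs. Ighm, of the plasma cell list, was bright on both arrays (9.83 in CD8+ and 9.93 in CD8- DCs). NK cells in the CD8- sort would likewise bring their abundant transcripts. The median over 12 genes was -0.0493, with Nkg7 at 2.34 and Gzma at 3.10 in CD8- DCs, although Klrk1 was 1.66-fold higher there. The 3 B cell genes and the 3 NK cell genes past 2-fold had medians of 4.20 and 2.74, and both gaps to the whole list exceeded its SD. Those genes were picked by their difference, so a gap follows from the selection and decides nothing. The gates removed B220+ and CD3+ cells but had no NK cell marker. Expression of Cd22, Cd72 and Klrd1 by CD8- DCs themselves may account for the values of these genes and was not tested. The source of Cd79b was not tested either.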
